A study of Gallus gallus with 20 samples.

How the data were processed

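Chicken embryos were White Leghorn, and tissue was taken on embryonic day 16. Per the labels, RCAS virus was injected into the amniotic cavity or the hind limb on embryonic day 3, or plasmid was delivered with electroporation, and RA was given into the amniotic cavity on embryonic day 9. Total RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA V2 kit. Per the submitters' processing notes, reads were aligned with TopHat2 to the chicken genome build galGal4 and quantified in Partek as RPKM; versions and settings are not given in the sources used here. The analysis here began from the 2 processed tables, 1 of all genes and 1 of keratins, and raw reads were not used here. All 180 keratins had identical values in both tables, and values were given to 1 decimal. Neither table pairs the 16110 Ensembl identifiers with symbols, and the reference table of symbols holds no such identifier.

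All tests used log2(RPKM + 1). Genes with RPKM of at least 1 in at least 2 libraries were kept (11863 of 16290, among them 163 keratins: 84 feather, 12 claw, 3 feather-like, 14 keratinocyte, 16 scale, 33 alpha and 1 other). limma with an intensity trend was fitted to all 20 libraries in 9 groups (11 residual degrees of freedom, prior 5.35), with the Benjamini-Hochberg adjustment over genes within each comparison and a threshold of 0.05. With 2 libraries against 2 the smallest possible two-sided exact p is 0.333, so calls rest on limma's pooled spread and no rank test was used. Replicate numbers were not used as pairs. Keratins were also fitted alone without the trend; counts of higher and lower keratins come from that fit, adjusted over the 163 keratins, and p-values and SE of single keratins from the fit over all genes. Classes were tested with fry, which asks whether members move one way on balance, without comparing them with other genes, adjusted over 48 tests (6 classes in 8 comparisons). Of 28 gene lists fixed before the data were examined, only the alpha-keratin list matched enough genes to test (20); the basal epidermis list matched 3 and the others 0, so these lists are not assessed. Camera used its preset correlation of 0.01, adjusted over 8 tests.

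Keratins were named by a rule fixed beforehand: the 10 largest rises and 10 largest falls with adjusted p below 0.05, all libraries on one side of both GFP libraries and a mean of at least 1 RPKM in one group. Genes named outside it are said to have been chosen after their values were seen. Median-ratio scaling used 11635 genes, and scaled tests covered 11687 genes. The shift along the feather axis used the mean differences of each group and GFP, with the covariance from shared controls (0.0140) subtracted. Simulated groups without effect gave shifts between -0.00912 and 0.00939. These draws treat genes as independent and hold no variation of whole libraries, so this range is too narrow.

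After the first complete run the adjustment families of fry were separated into classes and chromosome groups, and the camera setting with a robust prior and the axis settings with 2 groups or a robust prior were not run. The reading of the keratin pairs was later changed from 1 pair to all 4 found within 2% of each other in the feather and RA libraries, without comparing sequences. The pairs were then read as not deciding on read assignment as a cause of the second set of 25 genes. Only 1 of the 2 pairs that split was measured in GFP libraries. The overlap with different GFP libraries was added then, by a fit with each GFP library as its own group (10 residual degrees of freedom). Alternatives fixed before the data were examined were a filter at a mean RPKM of 5, no filter, a pseudocount of 0.1, median-ratio and quantile scaling, a replicate block, only the 2 groups compared, a robust prior, an estimated correlation for camera, 2 other axes, and leaving out each of the 20 libraries; 5 more were chosen after the data were seen.

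Known answers were planted to check the code. Of 200 genes shifted in simulated data, limma recovered between 47.8% and 76.1% at a log2 change of 0.5. It recovered between 89.6% and 98.5% at 1 and between 97.0% and 100% at 2, with 1.81% to 6.08% wrong calls. The shifted genes had a GFP mean above 2.5 in log2(RPKM + 1), so recovery at lower levels is not shown. These draws also treat genes as independent and hold no variation of whole libraries. The fry test recovered a claw shift of -1 in 8 of 8 comparisons, with 1 of 40 other classes called, camera recovered a shift of 0.5 in 20 genes in 8 of 8 with 0 of 7 others called, and an axis shift of 0.3 came back as 0.298 to 0.302 on average. The searches for dividing genes found 20 of 20 planted genes with 0 others, and the search for keratins with near-equal values 4 of 4 pairs. Analyses ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.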

Results

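The series measured RNA from skin appendages of White Leghorn chicken embryos on embryonic day 16, to set scales given a gene or retinoic acid against control scales and normal feathers. Scutate scales are the large overlapping plates on the front of the bird foot, and feather tissue was dissected as dorsal skin, so tissue and body site differed together. The 20 libraries fell into 9 groups. Control scales carried the green fluorescent protein (GFP) in RCAS, an avian retroviral vector (n = 2). Scales misexpressing 1 gene each came from RCAS with beta-catenin, the transcriptional effector of Wnt signalling (n = 2), Grem1, a secreted antagonist of bone morphogenetic proteins (n = 2), Spry2, a feedback inhibitor of receptor tyrosine kinase signalling (n = 2), the transcription factors Sox2 (n = 2) and Sox18 (n = 3), and a construct named Zic1-deltaC (n = 3). Scales from embryos given retinoic acid (RA), a vitamin A derivative, on embryonic day 9 (n = 2) had no vehicle control among the groups, and normal feather completed the set (n = 2). The labels give no virus for the RA and feather groups, so their comparisons with GFP scales also differ in viral infection.

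Expression was given as RPKM, reads mapped per length of gene model and per library total, for 16290 genes. Of these, 180 carried keratin names, and the other 16110 carried Ensembl identifiers that the files do not pair with gene names. The genes delivered by the viruses were therefore not looked up here, and the labels were not checked that way. Keratin names gave the chromosome and the class, as in Chr25_Claw4. The beta-keratins, hard structural proteins of birds and reptiles, were read from these names as feather keratins (FK), claw keratins, scale keratins, feather-like keratins (FL) and keratinocyte keratins (Ktn). The KRT genes are alpha-keratins, which form the intermediate filaments of all vertebrate epidermis. Read totals were not analysed here and depth is unknown. RPKM summed to between 373550 and 750920 per library. Pearson's r of log2(RPKM + 1) across genes, which are not independent replicates, lay between 0.989 and 0.996 within groups and between 0.688 and 0.964 between groups. Levels below are means ± SD over the libraries of a group. Nothing in the labels says that replicates came from separate embryos, so p-values measure only the spread between these samples. All libraries of each keratin named with a p-value under the naming rule lay on one side of both GFP libraries.

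Keratin transcripts made up very different shares of the summed RPKM. The share was 74.4% and 68.8% in the feather libraries, 49.6% and 50.8% with RA, 45.2%, 42.0% and 35.8% with Sox18, and 31.0% and 29.9% with beta-catenin. In GFP scales it was 22.3% and 25.3%, with Grem1 18.6% and 20.6%, with Zic1-deltaC 19.5%, 18.0% and 16.7%, with Spry2 10.9% and 16.5%, and with Sox2 5.91% and 4.39%. Because RPKM is relative, a larger keratin share lowers the values of other genes, so each count of genes is given as given and after scaling each library by its median ratio to the others.

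**Figure D1:**
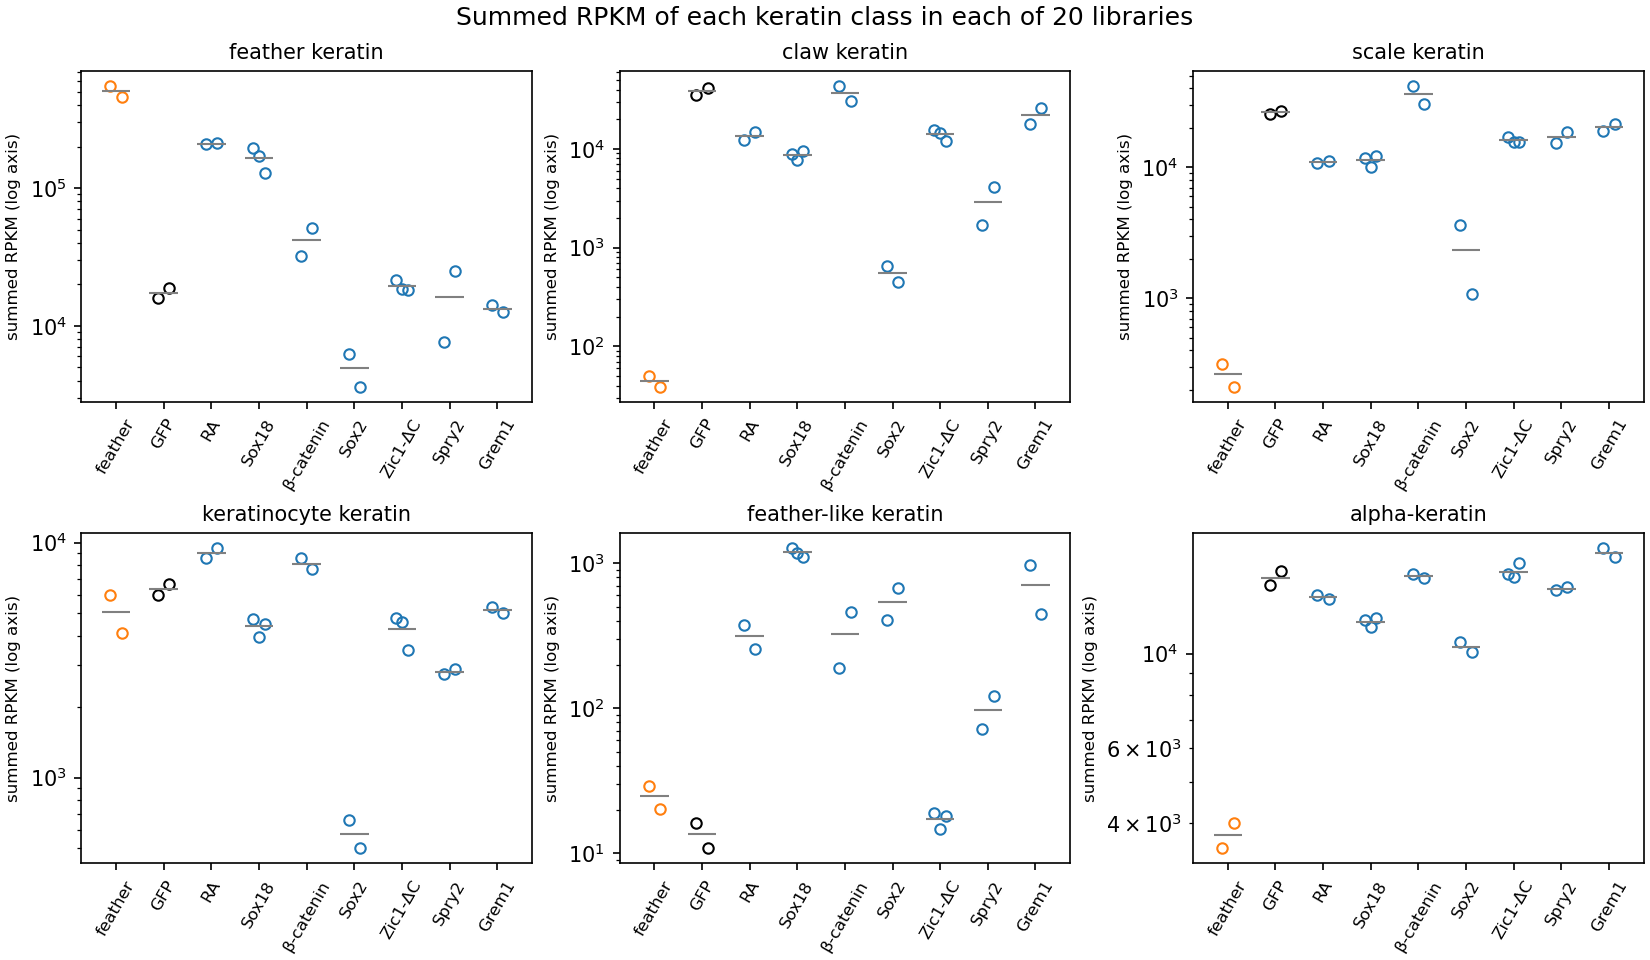
Summed RPKM of each keratin class (log axis) in each of the 20 libraries, 1 point per library, by group. Feather keratins sum to 505600 RPKM on average in feather and 17370 RPKM in GFP scales, whereas claw keratins sum to 44.4 RPKM in feather and 38400 RPKM in GFP scales.

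3 sets of genes without names set libraries apart, and each was found by searching the data. GFP replicate 1, a control in all 8 comparisons below, held 88 genes, 0 of them keratins, at 1 RPKM or more and over 4 times every other library, together 1561 RPKM. Of these, 41 were at 0.20 RPKM or less elsewhere. The other 19 libraries had 0 to 2 such genes each. Another 25 genes were listed at 0 in all 14 libraries of the other groups and at 1 RPKM or more in all 6 beta-catenin, Grem1 and Spry2 libraries, where they summed to between 592 and 761 RPKM. A further 25 genes were high in the GFP, RA, Spry2 and beta-catenin libraries, summing to between 851 and 1649 RPKM, and at 9 RPKM or less in sum in the feather, Grem1, Sox18, Sox2 and Zic1-deltaC libraries.

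**Figure D2:**
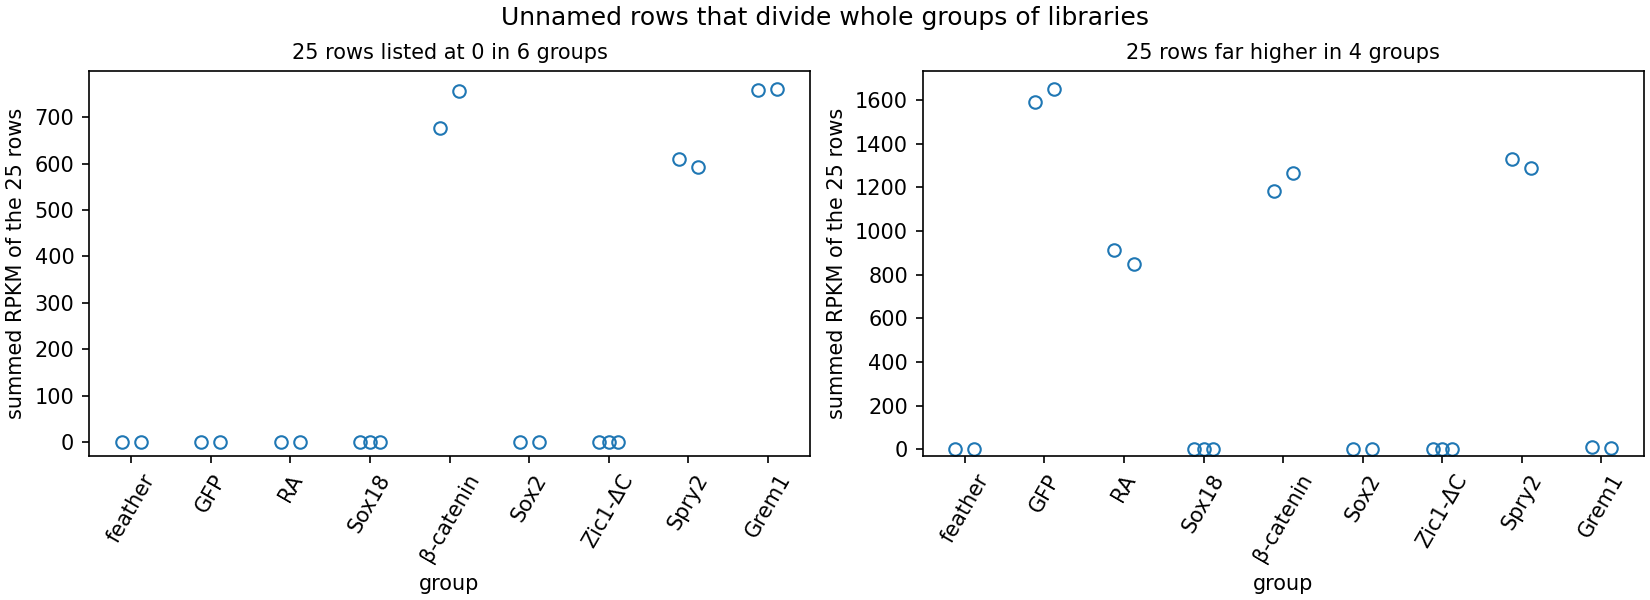
Summed RPKM (linear axis) of the 2 sets of 25 unnamed genes that divide whole groups, 1 point per library. One set lies between 592 and 761 RPKM in the 6 beta-catenin, Grem1 and Spry2 libraries and at 0 in the other 14; the other lies between 851 and 1649 RPKM in the GFP, RA, Spry2 and beta-catenin libraries.

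Feather was compared with the GFP scale to measure the span between both appendages. Feather keratins summed to 505600 ± 61050 RPKM in feather against 17370 ± 2005 RPKM in the GFP scale, 29.1-fold higher, and 70 of the 84 tested rose while 0 fell. Claw keratins, the main beta-keratins of the control scale by summed level, were 865-fold lower, at 44.4 ± 7.78 against 38400 ± 4653 RPKM, and all 12 fell. Scale keratins were 99.3-fold lower, at 264 ± 75.0 against 26210 ± 1179 RPKM, with 11 of 16 falling and 0 rising, or 6 falling and 1 rising after median-ratio scaling. ChrUn27_FK6 stood at 24435 ± 92.9 RPKM against 0.80 RPKM in both GFP libraries (log2 change 13.73, SE 1.34, limma adjusted p = 4.51e-08). Chr27_FK45 stood at 30940 ± 428 against 7.10 ± 1.84 RPKM (11.92, SE 0.71, limma adjusted p = 1.11e-10). Chr10_FK2 stood at 1356 ± 224 against 0.05 RPKM (10.33, SE 0.35, limma adjusted p = 1.84e-13). In the other direction, Chr25_Claw4 fell from 4422 ± 612 to 0.80 ± 0.141 RPKM (log2 change -11.26, SE 0.37, limma adjusted p = 1.2e-13). Chr25_Ktn15 went from 1610 ± 254 to 1.05 ± 0.212 RPKM (-9.61, SE 0.31, limma adjusted p = 1.03e-13).

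By class, fry (limma's rotation test of a set) gave an adjusted p of 9.76e-07 for feather keratins, whose mean log2 change was 5.09, of 2.29e-09 for claw keratins (mean -9.76) and of 3.95e-06 for scale keratins (mean -2.95). The median scale keratin changed by -1.56, and by -0.47 after scaling. Keratinocyte keratins were mixed, with 4 of 14 rising and 8 falling (mean -2.23, fry adjusted p = 3.32e-07). Of 33 alpha-keratins 8 rose and 14 fell (mean -0.95, fry adjusted p = 2.66e-08), but this direction flips with median-ratio scaling, to 15 rising and 12 falling and a mean of 0.09. KRT10, a keratin of differentiated epidermal layers in mammals, stood at 18.8 ± 4.45 against 2444 ± 321 RPKM (log2 change -6.96, limma adjusted p = 9.34e-14). KRT75B stood at 238 ± 86.6 against 0.60 ± 0.141 RPKM (7.18, limma adjusted p = 3.21e-12), and both KRT10 and KRT75B were named after their values were seen. None of the 3 feather-like keratins passed the test (mean 0.75, fry adjusted p = 0.155), and all 3 rose after scaling (mean 1.76, fry adjusted p = 0.00469). Over all 11863 genes tested, limma called 1148 higher and 9328 lower in feather, 11% higher. The log2 ratio of the scaling factors, feather to GFP, was -1.26, so scaling raised feather values against GFP. After scaling limma called 4213 higher and 4330 lower, 49.3% higher, and after quantile normalization 3703 and 4683. The second set of 25 unnamed genes divided these groups too, high in GFP scales and at most 9 RPKM in sum in feather.

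RA scales carried feather keratins at 12.1-fold the summed level of GFP scales, 210400 ± 1127 against 17370 ± 2005 RPKM, with 68 of 84 rising and 2 falling. Claw keratins were 2.81-fold lower in sum and all 12 fell, and the 3 feather-like keratins rose 23.2-fold in sum, from 13.6 ± 3.89 to 314 ± 82.9 RPKM. ChrUn27_FK6 reached 7484 ± 90.1 RPKM (log2 change 12.02, SE 1.34, limma adjusted p = 5.3e-06). Chr27_FK38 reached 2434 ± 224 against 0.10 RPKM (11.12, SE 1.08, limma adjusted p = 1.36e-06). Chr27_FK39 reached 6478 ± 389 against 2.15 ± 1.06 RPKM (11.05, SE 1.19, limma adjusted p = 3.85e-06). The largest fall was that of KRT4, which stands in mammals for internal stratified epithelia, from 130 ± 0.636 to 17.9 RPKM in both libraries (log2 change -2.80, SE 0.14, limma adjusted p = 1.71e-09). Chr25_scale8 went from 21.9 ± 8.41 to 3.80 ± 0.283 RPKM (-2.20, limma adjusted p = 0.000286). Chr27_FK12 went from 577 ± 143 to 134 ± 12.2 RPKM (-2.08, limma adjusted p = 0.00834). The call for Chr27_FK12 ended without GFP replicate 2 (limma adjusted p = 0.0554).

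Tested as sets, the mean log2 change was 4.22 for feather keratins (fry adjusted p = 5.49e-06), -1.49 for claw keratins (fry adjusted p = 0.0043) and 4.2 for feather-like keratins (fry adjusted p = 5.1e-06). Keratinocyte keratins rose in 6 of 14 and fell in 0 (mean 0.80, fry adjusted p = 0.00176). Scale keratins fell in 9 of 16 and rose in 0 (mean -0.84, fry adjusted p = 0.0349). This call ended after scaling (5 falling, mean -0.54, fry adjusted p = 0.214) and without either RA library (0.114 without replicate 1 and 0.091 without replicate 2) or either GFP library (0.0628 and 0.149). Alpha-keratins went both ways, 9 up and 7 down of 33, or 13 and 4 after scaling (mean 0.40, fry adjusted p = 0.0322). The alpha-keratin call ended without RA replicate 1 (0.148), GFP replicate 1 (0.096) or Sox18 replicate 3 (0.051). Across all genes limma called 989 higher and 6193 lower, 13.8% higher. Scaled values gave 2310 higher and 1976 lower, 53.9% higher. The log2 ratio of the scaling factors, RA to GFP, was -0.37, so scaling raised RA values against GFP. The majority turned with quantile normalization, to 1962 higher and 2695 lower.

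Sox18 scales had feather keratins at 165400 ± 33460 RPKM in sum, 9.52-fold the GFP level, and 61 of 84 rose while 4 fell. The feather-like keratins showed their highest rise here, 87.6-fold in sum to 1187 ± 84.0 RPKM, and all 3 rose. All 12 claw keratins fell, to a sum 4.41-fold lower, and 11 of 16 scale keratins fell while 0 rose. Chr27_FK39 reached 3056 ± 460 RPKM (log2 change 9.95, SE 1.09, limma adjusted p = 1.99e-06), and Chr27_FK47 was listed at 0 in both GFP libraries and at 389 ± 30.6 RPKM with Sox18 (limma adjusted p = 2.54e-11). Single feather keratins moved the other way. Chr27_FK13 stood at 0.10 ± 0.173 RPKM against 1037 ± 237 RPKM (log2 change -9.87, SE 0.34, limma adjusted p = 8.78e-13). It was also lower with RA, beta-catenin, Sox2, Zic1-deltaC, Spry2 and Grem1, each against the same GFP libraries. The RA call ended with a pseudocount of 0.1. A fall shared by so many groups may reflect its level in those libraries, which was not tested. Chr27_FK12 stood at 11.4 ± 2.02 against 577 ± 143 RPKM (-5.53, limma adjusted p = 8.75e-07). KRT79 fell from 21.8 ± 12.2 to 1.03 ± 0.153 RPKM (log2 change -3.38, SE 0.32, limma adjusted p = 4.05e-07). Chr25_scale18 went from 1298 ± 263 to 223 ± 12.1 RPKM (-2.52, limma adjusted p = 2.79e-05).

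The class tests gave a mean log2 change of 3.10 for feather keratins (fry adjusted p = 7.98e-05), 6.13 for feather-like keratins (fry adjusted p = 1.22e-07), -2.15 for claw keratins (fry adjusted p = 0.000215) and -1.26 for scale keratins (fry adjusted p = 0.00176). Keratinocyte keratins (4 up, 6 down of 14, but 5 up and 3 down after scaling, mean -0.21, fry adjusted p = 0.147) did not pass the test, but did when Sox2 replicate 1 or replicate 2 was left out (0.0335 in each case). Alpha-keratins (10 up, 11 down of 33, mean 0.35, fry adjusted p = 0.127) passed after scaling (mean 0.54, fry adjusted p = 0.000125) and without beta-catenin replicate 1 (0.0427) or 2 (0.0411) or Grem1 replicate 1 or 2 (0.0498 in each case). Over all genes, 1456 were higher and 4904 lower by limma, 22.9% higher. Scaled values gave 2820 and 2920, 49.1% higher, and quantile normalization 2705 and 3099. The log2 ratio of the scaling factors, Sox18 to GFP, was -0.22, so scaling raised Sox18 values against GFP. Again the second set of 25 unnamed genes was high in GFP and low in these libraries.

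Beta-catenin scales raised feather keratins less by summed level, 2.41-fold to 41860 ± 13490 RPKM, with 50 of 84 rising and 6 falling. Claw keratins stayed at 36770 ± 9026 against 38400 ± 4653 RPKM with 1 of 12 past the test, and 4 of 16 scale keratins rose while 0 fell. All 3 feather-like keratins rose, to 325 ± 193 RPKM in sum, 24.0-fold the GFP level (14-fold by replicate 1 alone and 34.0-fold by replicate 2). ChrUn27_FK6 was at 771 ± 405 RPKM (log2 change 8.64, SE 1.34, limma adjusted p = 0.00028). Chr27_FK39 stood at 1260.0 ± 629 RPKM (8.59, SE 1.19, limma adjusted p = 0.000105). Chr27_FK45 stood at 2125 ± 898 RPKM (7.99, SE 0.71, limma adjusted p = 9.88e-07). Chr27_FK45 and Chr27_FK46 had values within 2% of each other in the feather and RA libraries, and their sequences were not compared. Their ratio was between 4.42 and 6.79 in the beta-catenin, Grem1 and Spry2 libraries and between 0.971 and 1.04 elsewhere. Among falls, Chr27_FK2 went from 751 ± 116 to 31.6 ± 1.41 RPKM (log2 change -4.52, SE 0.62, limma adjusted p = 9.47e-05). Chr27_FK13 went to 233 ± 34.3 RPKM (-2.14, limma adjusted p = 0.000685), a call that ended with a pseudocount of 0.1 (0.0584). KRT15, a basal-layer keratin in mammals, went from 728 ± 65.3 to 360 ± 11.3 RPKM (-1.01, limma adjusted p = 0.000477). KRT4 went from 130 ± 0.636 to 77.8 ± 9.12 RPKM (-0.74, limma adjusted p = 0.00162).

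As sets, feather keratins changed by a mean log2 of 2.16 (fry adjusted p = 0.00234), feather-like keratins by 4.24 (fry adjusted p = 5.1e-06) and keratinocyte keratins by 0.89, with 6 of 14 rising and 0 falling (fry adjusted p = 0.000849). Claw keratins (mean -0.05, fry adjusted p = 0.92) and alpha-keratins (7 up, 5 down, mean 0.29, fry adjusted p = 0.155) did not pass. After scaling the claw mean flips to 0.05 and the alpha-keratins pass (0.00698). The claw mean also turns positive without beta-catenin replicate 2 (0.20) or GFP replicate 2 (0.07). The scale keratin call (mean 0.65, fry adjusted p = 0.0398) ended after scaling (0.0613), without beta-catenin replicate 1 (0.206), GFP replicate 1 (0.16) or GFP replicate 2 (0.0721), and without RA replicate 1 or 2, any Sox18 library, or Zic1-deltaC replicate 1 or 2 (0.0501 to 0.0563). Over all genes limma called 946 higher and 1802 lower, 34.4% higher, and after scaling 1655 and 1474, 52.9% higher. Quantile normalization gave 1440 and 1908. Without GFP replicate 1 it called 1515 in all, without beta-catenin replicate 2 1525 and without beta-catenin replicate 1 1736. The 25 genes listed at 0 outside the beta-catenin, Grem1 and Spry2 libraries count among the higher ones here and in both of those other comparisons.

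Sox2 scales lost most beta-keratin transcripts. Claw keratins were 69.4-fold lower in sum, at 554 ± 144 RPKM, and all 12 fell. Scale keratins were 11.1-fold lower, at 2353 ± 1815 RPKM, with 15 of 16 falling (7.21-fold by replicate 1 alone and 24.5-fold by replicate 2), and keratinocyte keratins 10.9-fold lower with 12 of 14 falling and 1 rising. Feather keratins were 3.51-fold lower with 41 of 84 falling and 6 rising. Feather-like keratins moved the other way, 39.9-fold up in sum, and 16 of 33 alpha-keratins rose while 11 fell. Chr25_Claw12 went from 4395 ± 352 to 3.05 ± 2.47 RPKM (log2 change -10.23, SE 0.39, limma adjusted p = 4.06e-12). Chr27_FK13 went to 1.1 ± 1.27 RPKM (-9.08, SE 0.37, limma adjusted p = 9.09e-12). Chr27_FK14 went from 369 ± 161 RPKM to a listed 0 in both libraries (limma adjusted p = 7.46e-09). Among rises, Chr25_Ktn14 went from 0.20 ± 0.141 to 71.8 ± 0.495 RPKM (log2 change 5.93, SE 0.21, limma adjusted p = 1.78e-12). KRT16A, of a gene family induced in injured epidermis in mammals, went from 9.85 ± 1.63 to 326 ± 55.6 RPKM (4.91, SE 0.39, limma adjusted p = 4.95e-08). KRT73 went from 5.05 ± 0.636 to 152 ± 29.7 RPKM (4.65, limma adjusted p = 1.02e-07). KRT7, a keratin of simple epithelia in mammals, went from 1.20 ± 0.141 to 28.9 ± 4.67 RPKM (3.76, limma adjusted p = 3.83e-13). ChrUn27_FK6 had a log2 change of 3.90 (limma adjusted p = 0.0204), and of 3.5 after scaling (0.0529) and 2.43 without Sox2 replicate 1 (0.201). Without GFP replicate 1 or 2 its change was still 3.90, but the adjusted p lay above 0.05 (0.065 and 0.0685).

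The fry test called all 6 classes, with mean log2 changes of -7.14 for claw (adjusted p = 2.66e-08), -2.95 for scale (adjusted p = 3.87e-06), -2.75 for keratinocyte (adjusted p = 1.22e-07), -2.37 for feather (adjusted p = 0.000317), 4.39 for feather-like (adjusted p = 3.95e-06) and 0.64 for alpha-keratins (adjusted p = 0.000124). The summed level of alpha-keratins was nonetheless 1.45-fold lower, at 10380 ± 412 against 15060 ± 807 RPKM. Over all genes limma called 5751 higher and 1236 lower, 82.3% higher. Scaled values gave 2073 higher and 2519 lower, 45.1% higher. The log2 ratio of the scaling factors, Sox2 to GFP, was 0.34, so scaling lowered Sox2 values against GFP. The majority depended on the scaling, since quantile normalization gave 3339 higher and 2050 lower. Here too the second set of 25 unnamed genes was high in GFP and low in the treated libraries.

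Zic1-deltaC scales kept feather keratins near the control level in sum, 19460 ± 1894 against 17370 ± 2005 RPKM, while single members moved far in both directions, with 19 of 84 up and 12 down. All 12 claw keratins fell, to a sum 2.74-fold lower, 6 of 16 scale keratins fell and 0 rose, and 6 of 14 keratinocyte keratins fell and 0 rose. Chr27_FK1 went from 4.65 ± 4.17 to 1192 ± 153 RPKM (log2 change 7.94, SE 1.16, limma adjusted p = 0.000123). Chr25_FK9 went from 27 ± 12.4 to 314 ± 27.3 RPKM (3.56, limma adjusted p = 0.000123). KRT84, of a family of hard keratins in mammalian hair and nail, went from 2.90 ± 0.849 to 53.3 ± 12 RPKM (3.79, SE 0.32, limma adjusted p = 4.04e-07). KRT13C went from 31.8 ± 14.7 to 280 ± 44.5 RPKM (3.16, limma adjusted p = 1.69e-07). Falls included Chr27_FK13, to 0.333 ± 0.153 RPKM (log2 change -9.59, SE 0.34, limma adjusted p = 1.4e-12), Chr27_FK12, to 17.4 ± 5.43 RPKM (-4.99, limma adjusted p = 9.1e-06), and Chr27_FK21, from 197 ± 99.5 to 7.53 ± 2.07 RPKM (-4.47, limma adjusted p = 3.24e-07).

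The claw keratins had a mean log2 change of -1.44 (fry adjusted p = 0.00311), keratinocyte keratins of -0.65 (fry adjusted p = 0.00182) and scale keratins of -0.89 (fry adjusted p = 0.0165). Scale keratins did not pass without GFP replicate 2 (0.0975). Feather keratins did not move one way on balance (mean 0.30, fry adjusted p = 0.791), while fry's test for change in either direction gave an unadjusted p of 1.19e-14. A small value was not particular to Zic1-deltaC. In the other comparisons that fry test gave feather keratins unadjusted p-values from 3.91e-12 (Spry2) to 1.1e-07 (beta-catenin). Feather-like keratins (0 of 3 called, mean 0.28, fry adjusted p = 0.532) and alpha-keratins (10 up, 6 down, mean 0.25, fry adjusted p = 0.109) did not pass. Over all genes limma called 1760 higher and 1175 lower, 60% higher, and after scaling 1665 and 1657, 50.1% higher. Quantile normalization gave 1944 and 1572. Without GFP replicate 2 it called 1271 genes in all, and 46 keratins in place of 71, and the calls for Chr27_FK14 and Chr27_FK15, 2 of the 10 largest keratin falls, ended. The second set of 25 unnamed genes divided GFP from these libraries as well.

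Spry2 scales had claw keratins 13.2-fold lower in sum, at 2901 ± 1707 RPKM, and all 12 fell (22.7-fold by replicate 1 alone and 9.35-fold by replicate 2). Of 16 scale keratins 8 fell and 1 rose, of 14 keratinocyte keratins 7 fell and 2 rose, and of 33 alpha-keratins 12 rose and 6 fell. Feather keratins went both ways, 30 up and 25 down of 84, and their sum differed widely between both libraries, 16310 ± 12280 RPKM. Chr25_Claw10 fell from 1540 ± 169 to 58.8 ± 35.1 RPKM (log2 change -4.82, SE 0.31, limma adjusted p = 1.59e-08). Chr25_scale7 went from 24.8 ± 7.35 to 0.05 ± 0.0707 RPKM (-4.59, limma adjusted p = 7.46e-07). Chr27_FK13 went to 1.30 ± 0.990 RPKM (-8.87, SE 0.37, limma adjusted p = 2.8e-11). Chr27_FK2 went from 751 ± 116 to 4.50 ± 4.81 RPKM (-7.43, limma adjusted p = 3.13e-07). ChrUn27_FK6 rose to 1114 ± 828 RPKM (log2 change 9.04, SE 1.34, limma adjusted p = 0.000122). Chr27_FK45, whose ratio to Chr27_FK46 differed in these libraries as stated for beta-catenin, went to 1784 ± 1299 RPKM (7.58, limma adjusted p = 1.03e-06). KRT1 was at 625 ± 56.2 against 148 ± 21.6 RPKM (log2 change 2.07, limma adjusted p = 3.46e-05). KRT6B stood at 700.2 ± 10.2 against 132 ± 24.0 RPKM (2.41, limma adjusted p = 9.15e-06), and both KRT1 and KRT6B were named after their values were seen.

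Set tests gave mean log2 changes of -3.96 for claw (fry adjusted p = 3.23e-06), -1.52 for scale (fry adjusted p = 0.00245), -0.92 for keratinocyte (fry adjusted p = 0.000317), 2.67 for the 3 feather-like keratins, all of which rose (fry adjusted p = 0.000261), and 0.51 for alpha-keratins (fry adjusted p = 0.00106). For feather keratins the mean was 0.32 while fry's direction was down (adjusted p = 0.932), and the mean turned to -0.40 without Spry2 replicate 2. Limma called 2122 genes higher and 879 lower, 70.7% higher, and after scaling 1487 and 1495, 49.9% higher. The log2 ratio of the scaling factors, Spry2 to GFP, was 0.12, so scaling lowered Spry2 values against GFP. Quantile normalization gave 1678 and 1500. Without Spry2 replicate 1 the total was 1600, without GFP replicate 2 1736 and without Spry2 replicate 2 1998. The 25 genes listed at 0 outside the beta-catenin, Grem1 and Spry2 libraries belong to the higher genes.

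Grem1 scales raised alpha-keratins and feather-like keratins. Of 33 alpha-keratins 14 rose and 3 fell, all 3 feather-like keratins rose, 52.6-fold in sum to 713 ± 376 RPKM (72.2-fold by replicate 1 alone and 33.0-fold by replicate 2), and of 84 feather keratins 10 rose and 25 fell. Chr25_FL2 went from 6.35 ± 1.48 to 576 ± 291 RPKM (log2 change 6.21, SE 0.42, limma adjusted p = 1.52e-08). KRT73 went to 150.2 ± 94.9 RPKM (4.49, SE 0.39, limma adjusted p = 3.88e-07). KRT16B went from 1.25 ± 0.212 to 32.3 ± 6.08 RPKM (3.88, limma adjusted p = 1.13e-05). KRT13C went to 359 ± 28.6 RPKM (3.53, limma adjusted p = 7.44e-08). Chr25_scale10 went from 0.75 ± 0.0707 to 18.1 ± 3.96 RPKM (3.43, limma adjusted p = 6.09e-09). Chr27_FK1 rose to 454 ± 174 RPKM (log2 change 6.51, SE 1.27, limma adjusted p = 0.00115). Chr27_FK13 fell to 0.65 ± 0.212 RPKM (log2 change -9.28, SE 0.37, limma adjusted p = 5.96e-12). Chr27_FK21 went from 197 ± 99.5 to 0.35 ± 0.495 RPKM (-7.15, SE 0.40, limma adjusted p = 1.06e-09).

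In the set tests alpha-keratins had a mean log2 change of 0.94 (fry adjusted p = 1.95e-06) and feather-like keratins of 4.89 (fry adjusted p = 1.95e-06). Feather-like keratins rose in every treated group except Zic1-deltaC, always against the same GFP libraries, at 13.6 ± 3.89 RPKM in sum. In Zic1-deltaC they summed to 17.2 ± 2.25 RPKM and in feather to 24.7 ± 6.22 RPKM. The other classes did not pass: feather (mean -0.55, fry adjusted p = 0.13), claw (1 up, 5 down, mean -0.77, fry adjusted p = 0.0972), keratinocyte (1 up, 4 down, mean -0.34, fry adjusted p = 0.0756) and scale (3 up, 1 down, mean 0.22, fry adjusted p = 0.448). Leaving out either Spry2 library brought claw (0.0313) and keratinocyte keratins (0.0456) past the test. Leaving out either Sox2 library (0.0493) or Sox18 replicate 2 (0.047) did so for keratinocyte keratins. The scale mean turned to -0.01 without Grem1 replicate 2. Limma called 1561 genes higher and 2163 lower, 41.9% higher, and after scaling 2227 and 1973, 53.0% higher. Quantile normalization gave 2126 and 2113. Without Grem1 replicate 1 the total was 2227 and without GFP replicate 1 2358. Both sets of 25 unnamed genes moved with this comparison, the first up and the second down.

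**Figure D3:**
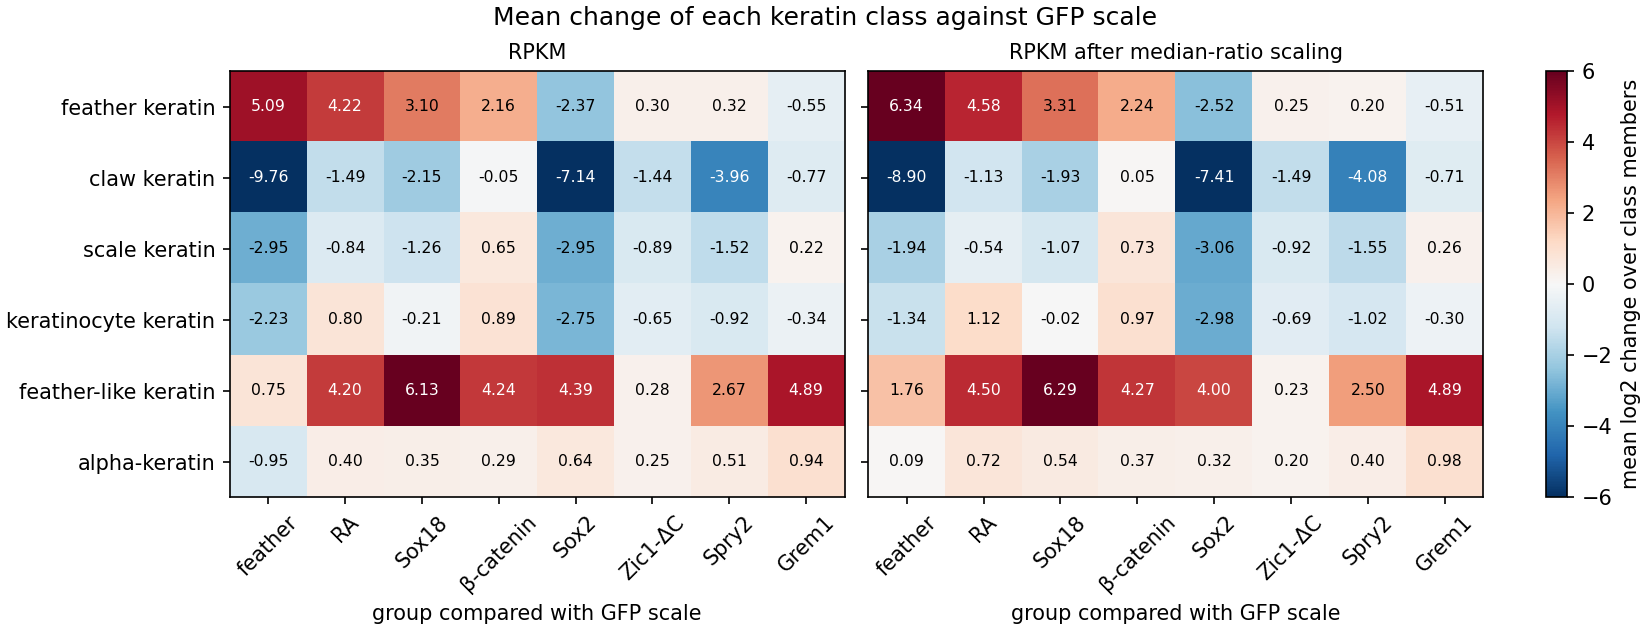
Mean log2 change of each keratin class against the GFP scale (colour), in 8 groups, as given and after median-ratio scaling. Claw keratins fall most in feather (-9.76) and Sox2 (-7.14), feather keratins rise most in feather (5.09), RA (4.22) and Sox18 (3.10), and the sign flips with scaling for alpha-keratins in feather (-0.95 to 0.09) and claw keratins with beta-catenin (-0.05 to 0.05).

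A list of 28 alpha-keratin symbols, fixed before the data were examined, matched 20 genes and was set against all other genes with camera, limma's competitive set test. With Grem1 11 members were higher and 3 lower, 12 and 3 when adjusted over the list alone, and camera gave an adjusted p of 0.000225 (median log2 change 0.47), but camera adjusted p = 0.26 with an estimated correlation. The other 7 comparisons did not pass, with camera adjusted p between 0.181 with RA and 0.906 with Sox18 and Zic1-deltaC. Counts of higher and lower members were 3 and 12 in feather (2 and 12 adjusted over the list alone), 1 and 5 with beta-catenin (1 and 6), 3 and 7 with RA (3 and 7), 4 and 10 with Sox18 (5 and 10), 10 and 8 with Sox2 (10 and 8), 4 and 5 with Spry2 (4 and 6) and 5 and 4 with Zic1-deltaC (5 and 5). Camera works on moderated t values and sets the list against the other genes, so its direction can differ from that of the mean log2 change. It was up in feather, where the mean was -1.83 for the list and -0.85 for other genes, down with Sox2 (0.32 and 0.19) and down with Zic1-deltaC (0.08 and 0.03). In the other 5 comparisons it had the direction of the list's mean relative to other genes, as with RA (-0.20 and -0.24, up) and Spry2 (-0.05 and 0.10, down).

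Each treated scale was also compared with normal feather. Before scaling, RA and Sox18 scales differed from feather in the fewest keratins. With RA 58 of 163 were higher and 46 lower, and with Sox18 54 were higher and 59 lower. With beta-catenin 58 were higher and 72 lower, with Grem1 60 and 83, with Zic1-deltaC 46 and 88, with Spry2 51 and 92, and with Sox2 50 and 101. After scaling the same counts were 45 and 66 with RA, 47 and 92 with Sox18, 48 and 92 with beta-catenin, 47 and 94 with Grem1, 40 and 106 with Zic1-deltaC, 40 and 105 with Spry2, and 31 and 112 with Sox2. RA still differed in the fewest keratins then, while Sox18 lay close to beta-catenin and Grem1. Over all genes limma called 8504 higher and 966 lower with RA, 9005 and 1032 with Sox18, 9194 and 1138 with beta-catenin, 9310 and 1088 with Grem1, 9392 and 1159 with Zic1-deltaC, 9707 and 1017 with Spry2, and 9801 and 1031 with Sox2. These splits depended on scaling, which lowered the values of treated scales against feather. The log2 ratio of the scaling factors, treated to feather, was 0.89 (RA), 1.04 (Sox18), 1.16 (beta-catenin), 1.20 (Grem1), 1.32 (Zic1-deltaC), 1.38 (Spry2) and 1.60 (Sox2). Scaling left 3755 higher and 3948 lower with RA, 4318 and 4133 with Sox18, 4354 and 4268 with beta-catenin, 4387 and 4148 with Grem1, 4578 and 4422 with Zic1-deltaC, 4444 and 4255 with Spry2, and 4419 and 4355 with Sox2. Quantile normalization gave 3852 higher and 3474 lower with RA, 4662 and 3592 with Sox18, 4456 and 3933 with beta-catenin, 4779 and 3686 with Grem1, 5061 and 3861 with Zic1-deltaC, 4820 and 3723 with Spry2, and 5220 and 3583 with Sox2.

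Keratins called in the same direction in feather and in a treated scale, both against GFP, were counted among the 163 tested. RA shared 76 higher and 27 lower keratins with feather, where independent lists would share 43.8 and 8.28, and 0 that were higher in feather were lower with RA. Sox18 shared 69 higher and 36 lower (39.7 and 12.1 for independent lists), beta-catenin 55 and 5 (36.2 and 3.04), Spry2 38 and 27 (24.4 and 16.0), Zic1-deltaC 24 and 23 (14.8 and 11.6), Sox2 12 and 38 (13.2 and 25.1) and Grem1 17 and 12 (16.3 and 10.5). Keratins higher in feather but lower in the treated scale numbered 34 with Sox2, 19 with Grem1 and 18 with Spry2. In 100 simulated draws with feather and 1 treated group both set to the GFP mean, no keratin was called in both. Few calls could arise there at all, so the draws do not show what the shared GFP libraries add where feather differs. With feather set against 1 GFP library and the treated scale against the other, in both arrangements and chosen after the data were seen, the control is no longer shared and a lone GFP library is taken to vary like other groups. RA then shared 66 and 70 higher keratins (36.3 and 38.7 for independent lists) and 22 and 18 lower (6.96 and 5.40). Sox18 shared 56 and 63 higher (32.9 and 34.5) and 32 and 28 lower (10.6 and 9.18), and beta-catenin 42 and 49 higher (26.5 and 29.8) and 2 and 2 lower (1.8 and 1.62). Spry2 shared 29 and 33 higher (20.1 and 19.6) and 25 and 23 lower (15.5 and 13.2), and Zic1-deltaC 19 and 19 higher (12.8 and 10.7) and 19 and 10 lower (10.8 and 6.21). Sox2 shared 10 and 11 higher (12.3 and 11.7) and 34 and 34 lower (21.6 and 21.9), and Grem1 13 and 12 higher (12.8 and 11.2) and 9 and 5 lower (8.76 and 6.48). Keratins are not independent of each other, so these expected values are no test.

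How far each treated profile moved from GFP towards feather was measured over all 11863 genes as the covariance of both differences, less the part from shared controls, over the variance of the feather difference, so that 0 is the GFP scale and 1 is feather. The shift was 0.405 with RA (95% interval 0.398 to 0.411 from simulated draws), 0.385 with Sox18 (0.378 to 0.391), 0.164 with beta-catenin (0.156 to 0.172), 0.129 with Spry2 (0.121 to 0.136), 0.106 with Grem1 (0.0988 to 0.113), 0.0792 with Sox2 (0.0713 to 0.0872) and 0.0695 with Zic1-deltaC (0.0629 to 0.0761). The draws treat genes as independent, so these intervals are too narrow, and so are the ranges from draws of unchanged groups given below. Leaving out 1 library at a time moved the shift between 0.390 and 0.422 with RA, 0.365 and 0.407 with Sox18, 0.145 and 0.187 with beta-catenin, 0.0950 and 0.162 with Spry2, 0.0880 and 0.125 with Grem1, 0.0667 and 0.0955 with Sox2, and 0.0579 and 0.0856 with Zic1-deltaC. On an axis that shares no library with the treated minus GFP difference, feather against the other 6 treated groups, the shift was 0.389 with RA, 0.329 with Sox18, 0.113 with beta-catenin and 0.0332 with Spry2. On that axis it was 0.00787 with Grem1, 0.00444 with Zic1-deltaC and -0.00183 with Sox2. Draws of unchanged groups on the main axis spanned -0.00912 to 0.00939 over all groups, so no direction is read from these values. On the axis without GFP libraries 1 is not feather and the reference differs for each group. Its values therefore do not share the scale of the main shifts. Without both sets of 25 unnamed genes and 138 others that lay lower in the GFP, RA, Spry2 and beta-catenin libraries after scaling, an alternative chosen after seeing the data, the shift was 0.0444 with Zic1-deltaC, 0.0534 with Sox2, 0.0777 with Grem1, 0.368 with Sox18 and 0.413 with RA. The covariance itself was 0.612 with RA, 0.582 with Sox18, 0.256 with beta-catenin, 0.204 with Spry2, 0.170 with Grem1, 0.131 with Sox2 and 0.117 with Zic1-deltaC, against 0.0129 to 0.0138 in draws of unchanged groups. The correlations across genes behind these were 0.745, 0.678, 0.394, 0.297, 0.241, 0.138 and 0.208 in the same order, against 0.0623 to 0.0716 in those draws. Over keratins alone the shift was 0.497 with RA, 0.445 with Sox18, 0.312 with Spry2, 0.285 with Sox2, 0.235 with beta-catenin, 0.128 with Zic1-deltaC and 0.0571 with Grem1, and without them 0.316, 0.332, 0.0639, 0.0602, 0.0996, 0.0496 and 0.136. Falls shared with feather count towards the keratin shift as rises do. With Sox2 the mean log2 change was -7.14 for claw and -2.37 for feather keratins, against -9.76 and 5.09 in feather. With Spry2 these means were -3.96 and 0.32.

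**Figure D4:**
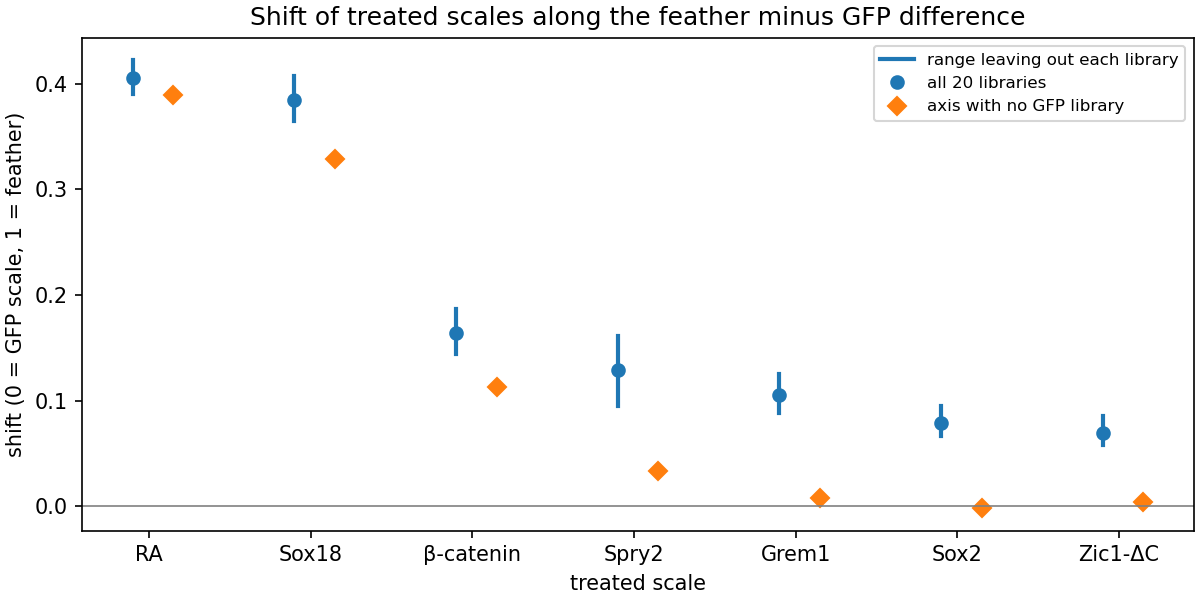
Shift of each treated scale along the feather minus GFP difference (0 is the GFP scale, 1 is feather), with the range over leave-one-out fits as bars. Diamonds show the axis without GFP libraries, on which 1 is not feather and the reference differs for each group. RA (0.405) and Sox18 (0.385) lie highest on both axes. On the axis without GFP libraries Sox2 lies at -0.00183, within the range of draws of unchanged groups on the main axis.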

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

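Alternatives were run on gene counts, keratin counts, named keratins, keratin classes against GFP, the alpha-keratin list and the shifts. Camera with a robust prior and the shifts with 2 groups or a robust prior were not run, and contrasts between treated groups were run only as given and with median-ratio scaling. Values that changed a call, a direction, or a count by more than 1.5-fold, or moved a shift beyond its interval, are given here. Shifts stand in the order beta-catenin, Grem1, RA, Sox18, Sox2, Spry2, Zic1-deltaC unless named.

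With the axis taken from feather against the other 6 treated groups the shifts were 0.113, 0.00787, 0.389, 0.329, -0.00183, 0.0332 and 0.00444. The sign for Sox2 reversed, but its value lay within the range of draws of unchanged groups on the main axis. With only genes called between feather and GFP they were 0.160 (beta-catenin), 0.0942 (Grem1) and 0.411 (RA). The estimated correlation ended the camera call for Grem1 (adjusted p = 0.26).

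With a mean RPKM of at least 5, and so fewer genes tested, limma called 6547 genes in feather, 1607 with beta-catenin, 2119 with Grem1, 4729 with RA, 4081 with Sox18, 4408 with Sox2, 1953 with Spry2 and 1874 with Zic1-deltaC against GFP. Against feather it called 6474, 6555, 6140, 6407, 6730, 6656 and 6574 in the order above. The alpha-keratin list passed camera with Sox2 (adjusted p = 0.0437) and Spry2 (adjusted p = 0.023), and the fry calls for alpha-keratins with RA (mean 0.41) and scale keratins with beta-catenin (mean 0.63) ended. Shifts were 0.171 (beta-catenin), 0.0918 (Grem1), 0.425 (RA), 0.398 (Sox18) and 0.0695 (Sox2). With no filter the list's direction reversed in feather (adjusted p = 0.869), the call for alpha-keratins with RA ended (mean 0.40), and shifts were 0.158 (beta-catenin), 0.394 (RA), 0.369 (Sox18), 0.0591 (Sox2), 0.114 (Spry2) and 0.0649 (Zic1-deltaC).

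With median-ratio scaling the camera direction reversed in feather (adjusted p = 0.593) and with Sox2 (adjusted p = 0.891), as did the mean of alpha-keratins in feather (0.092) and of claw keratins with beta-catenin (0.048). Calls were gained for alpha-keratins with Sox18 (0.54) and beta-catenin (0.37) and feather-like keratins in feather (1.76), and lost for scale keratins with RA (-0.54) and beta-catenin (0.73). limma called 4286 genes with RA and 4592 with Sox2, and shifts were 0.137, 0.0911, 0.370, 0.351, 0.0654, 0.105 and 0.0602. With quantile normalization the camera direction reversed in feather (adjusted p = 0.443), RA (0.791), Sox2 (0.698), Spry2 (0.791) and Zic1-deltaC (0.683). Calls were gained for alpha-keratins with Sox18 (0.35) and Zic1-deltaC (0.34) and feather-like keratins in feather (1.60), and lost for scale keratins with beta-catenin (0.65). The RA count was 4657 and shifts were 0.152, 0.112, 0.396, 0.390, 0.104, 0.124 and 0.0739.

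With a pseudocount of 0.1 calls were gained for alpha-keratins with Sox18 (0.39) and feather-like keratins in feather (1.24), and lost for scale keratins with RA (-0.97) and beta-catenin (0.81). The mean of keratinocyte keratins with Sox18 reversed (0.036). Shifts were 0.159 (beta-catenin), 0.138 (Grem1), 0.364 (RA), 0.371 (Sox18), 0.0987 (Sox2) and 0.0791 (Zic1-deltaC).

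With only the 2 groups compared limma called 2316 genes with Grem1, 1806 with Spry2 and 1234 with beta-catenin. Calls were gained for alpha-keratins with Sox18 (0.35) and Zic1-deltaC (0.25) and keratinocyte keratins with Grem1 (-0.34), and lost for scale keratins with beta-catenin (0.65). The camera direction reversed with Sox18 (adjusted p = 0.914). A robust prior changed no class and no count.

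Treating replicate numbers as a block or pairing reversed the camera direction with Sox18 (adjusted p = 0.978), ended the scale keratin call with beta-catenin (0.65) and gave shifts of 0.392 (Sox18) and 0.0764 (Zic1-deltaC). Over 36 pairs of groups the correlation of replicate differences lay between -0.279 and 0.213, so the numbers were not used as pairs.

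Removing both sets of 25 unnamed genes and 138 others that lay lower in the GFP, RA, Spry2 and beta-catenin libraries after scaling, an alternative chosen after seeing the data, gave shifts of 0.0777 (Grem1), 0.413 (RA), 0.368 (Sox18), 0.0534 (Sox2) and 0.0444 (Zic1-deltaC).

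Of the named keratins, calls that ended were mostly beta-catenin ones near the threshold. Chr27_FK9 and Chr25_Claw10 lost theirs with a pseudocount of 0.1, no filter, median-ratio scaling, a replicate block and a robust prior, and in 11 and 5 of the leave-one-out fits. Chr25_Claw10, Chr27_FK21, Chr27_FK38 and ChrUn27_FK13 lost theirs with only the 2 groups compared, Chr27_FK13 with a pseudocount of 0.1, and KRT12 and ChrUn27_FK13 in 2 leave-one-out fits each. With RA, Chr27_FK13 lost its call with a pseudocount of 0.1 and Chr27_FK12 in 1 leave-one-out fit. With Sox2, ChrUn27_FK6 lost its call with median-ratio scaling, only the 2 groups compared, a robust prior and in 3 leave-one-out fits, and with Zic1-deltaC Chr27_FK14 and Chr27_FK15 in 1 each.

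Leaving out 1 library at a time, with a lone remaining sample taken to vary like other groups, gave 1515 to 3262 genes with beta-catenin, 2227 to 4172 with Grem1, 1600 to 3562 with Spry2 and 1271 to 3392 with Zic1-deltaC (46 to 77 keratins). Shifts ranged from 0.145 to 0.187, 0.0880 to 0.125, 0.390 to 0.422, 0.365 to 0.407, 0.0667 to 0.0955, 0.0950 to 0.162 and 0.0579 to 0.0856. Class means whose call or direction changed ranged, with beta-catenin, from -0.30 to 0.20 (claw) and 0.42 to 0.88 (scale). With Grem1 they ranged from -1.06 to -0.48 (claw), -0.41 to -0.28 (keratinocyte) and -0.0095 to 0.44 (scale), and with RA from -0.95 to -0.73 (scale) and 0.35 to 0.45 (alpha). With Sox18 they ranged from -0.28 to -0.13 (keratinocyte) and 0.33 to 0.38 (alpha), with Spry2 from -0.40 to 1.05 (feather) and with Zic1-deltaC from -1.0 to -0.78 (scale).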

Other observations

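RA scales had more of some feather keratins than Sox18 scales, with 20 of 84 higher and 1 lower (mean log2 difference 1.11, fry adjusted p = 0.0283). The contrast and the grouping by the chromosome in the name were chosen after the data were seen, so the p-values of these groups are not independent tests. The 7 feather keratins named after chromosome 10 or its unplaced part (Un10) summed to 4627 ± 57.1 RPKM with RA and 297 ± 70.4 RPKM with Sox18, against 27.2 ± 0.707 RPKM in GFP scales and 35960 ± 6136 RPKM in feather. Against GFP they were also higher in sum with Sox18 (10.9-fold, 6 of 7 rising), Zic1-deltaC (7.53-fold, 4.03 to 11.1 by library, 5 of 7), beta-catenin (3.74-fold, 2.33 to 5.14 by library, 5 of 7) and Spry2 (3.46-fold, 4 of 7). All 7 were higher with RA than with Sox18 (mean 3.54, fry adjusted p = 6.92e-06, and 3.68 after scaling). ChrUn2_FK1 and ChrUn2_FK5, the only tested ones named after chromosome 2 or Un2, were higher with RA as well (mean 4.92, fry adjusted p = 5.17e-07) but passed the filter through the RA libraries. Those named after chromosome 27 (8 of 44 up, 0 down, mean 1.06, fry adjusted p = 0.0616) and Un27 (3 of 15 up, 1 down, mean 0.85, fry adjusted p = 0.0756) did not pass, but did after scaling (0.0368 and 0.0464). Those named after chromosome 25 did not pass (0 of 13 called, mean -0.08, fry adjusted p = 0.867, and the sign flips with scaling, to 0.06). The 3 feather-like keratins were lower with RA than with Sox18 (mean -1.94, fry adjusted p = 0.00149), and keratinocyte keratins were higher (8 up, 1 down, mean 1.01, fry adjusted p = 0.000224).

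Within the beta-catenin, Grem1 and Spry2 libraries, a set chosen after the data were seen, each group was tested against the mean of the other 2, which leaves GFP libraries out. Beta-catenin had more feather keratin (60 up, 0 down, mean log2 difference 2.28, fry adjusted p = 0.000275) and claw keratin (12 up, 0 down, mean 2.32, fry adjusted p = 0.000126). Grem1 had more alpha-keratin (17 up, 3 down, mean 0.54, fry adjusted p = 3.7e-05) and less feather keratin (2 up, 50 down, mean -1.79, fry adjusted p = 0.00204). Spry2 had less claw keratin (0 up, 12 down, mean -3.55, fry adjusted p = 6.92e-06), scale keratin (0 up, 11 down, mean -1.95, fry adjusted p = 0.000113) and keratinocyte keratin (0 up, 8 down, mean -1.19, fry adjusted p = 4.17e-05).

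The tests of causes here and for the patterns below were chosen after the patterns were seen. The 25 genes listed at 0 in 14 libraries were at 1 RPKM or more in all 6 beta-catenin, Grem1 and Spry2 libraries, and no other of 84 divisions of the groups gave any. Low values differed too, among 309 genes at 0 in some libraries and otherwise from 0.3 to under 1.8 RPKM. Of these, 64 to 88 were above 0 in each of the 6 libraries and 11 to 33 in each of the other 14. A different assignment of reads in the 6 beta-catenin, Grem1 and Spry2 libraries could also unbalance keratins with near-equal values elsewhere. At over 1.5-fold, 2 of 4 such pairs were unbalanced: Chr27_FK45 to Chr27_FK46 had a lowest ratio of 4.42 and ChrUn27_FK12 to ChrUn27_FK5 of 5.41. Chr27_FK40 to Chr27_FK41 (0.975 to 1.17) and Chr27_FK44 to ChrUn27_FK3 (0.954 to 1.13) stayed under 1.5-fold. In the GFP, Sox2, Sox18 and Zic1-deltaC libraries these 2 pairs lay, where measured, at 1.0 to 1.002 and at 1.0. All 4 pairs were thus less equal in the 6 libraries, 2 of them only slightly, and the pairs leave this cause open. Keratin comparisons of these groups with GFP would share any such difference. A shared response of the 3 groups was tested by the median range of their 3 group means over the 25 genes, which was 0.472 on the log2 scale, with 95.6% of 1000 random sets matched on level at or under it. That cannot tell a response from processing, because both follow the same groups.

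The second set of 25 genes was high in the GFP, RA, Spry2 and beta-catenin libraries, and the highest other of 126 divisions held 9. The sex of the embryos might divide whole groups in this way, for which a set of genes lower by up to 1.1 log2 in the same libraries would be a sign. Of these there were 94, with 0 lower by more, 3 higher by up to 1.1 and 6 higher by more, but the highest other division held 70 and the test required 1.5 times that, so it cannot tell. In the first search, which set no limit on the size of a fall, 138 genes lay lower after scaling, by -0.24 to -1.07. The next division into 4 and 5 groups held 121, whose falls reached -7.43. Among divisions into 3 and 6 groups, feather, RA and Sox18 held 263 lower genes, with falls to -2.75, and 29 far higher ones. For read assignment as in the first pattern, the pairs differed by at most 1.04-fold in the GFP, Sox2, Sox18 and Zic1-deltaC libraries. Of the 2 pairs that split there, only Chr27_FK45 and Chr27_FK46 had a ratio in GFP libraries, at low levels of 5.8 and 8.4 RPKM. The pairs alone therefore do not decide. The levels of these 25 genes argue against that difference as their sole cause. Grem1 libraries, inside the first division, held 9.0 and 7.7 RPKM in sum, against 1330.5 and 1289.6 RPKM with Spry2. GFP libraries, outside it, held 1589 and 1649 RPKM, against 1.2 RPKM in both Sox2 libraries.

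Feather values of most genes lay below those of GFP scales, with a median log2 change of -0.94 over the 11700 genes without keratin names. Since RPKM is relative, the keratin share could have caused this, and dividing each library by its sum without named keratins should then bring the median to 0. The median became -0.45, between -0.49 and -0.40 by feather library, so the share of the named keratins is excluded as the whole cause. Genes without names, any keratins among them included, stayed in the sum. The same division moved the median from -0.31 to -0.02 with RA, -0.20 to -0.05 with Sox18, -0.08 to -0.02 with beta-catenin, -0.05 to -0.02 with Grem1, 0.11 to 0.09 with Spry2 and 0.28 to 0.19 with Sox2, and away from 0 with Zic1-deltaC, 0.05 to 0.10. RPKM sums weight short genes more than a share of reads does, and read counts per gene would settle the rest.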
